A study of Mus musculus with 16 samples.

How the data were processed

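Total RNA of mouse brain cortex was extracted with a column kit and DNase treatment and sequenced on a HiSeq2500, per the labels' protocols. The submitters' processing notes name RSEM 1.2.19, edgeR and the builds mm10 and GRCm38, without saying how they were used. The gene annotation release and the strandedness of the libraries are not given in the sources used here. The deposited tables are 4 sheets, 1 per pairwise comparison, each with a column per animal.

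Each value is a normalized count, a signal that the authors made by dividing the gene counts by a factor per library, per the file headers and the steps in the values. The sheets were normalized separately, and the factor of a library differed between sheets by at most 0.23%. Each pairwise comparison was tested within its own sheet, and the interaction took the knockout libraries from the knockout sheet and the wild type libraries from the wild type sheet. The log2 ratio, a log2 value the authors gave for the first named group over the second, and the authors' p-value and false discovery rate were used only as deposited and described as theirs. The GC fraction of each gene, per the file headers, was not used in a test. The gene length in bases, a deposited column, was used for the length trend. A further 64 per-sample columns of FPKM values in the sheets were not used here.

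The low values of every library were whole multiples of 1 step, so whole reads were recovered by dividing by that step. In each of the 16 libraries 100% of the values up to 20 reads came out whole within 0.1 read. The step of WT_SD 3 was close to 1. Recovered totals ran from 8.76 to 30.5 M reads per library, and both ends of that range were libraries labelled knockout. A chi-square comparison of recovered reads between replicates of a group gave at least 7.94 per degree of freedom for every pair, so no library was counted as a duplicate.

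The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend and robust empirical Bayes on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low counts. Genes with a normalized count of at least 10 in at least 4 libraries of the comparison were tested. Each pairwise fit held only the 8 libraries of its groups, and the interaction fit held all 16. The 4 pairwise comparisons and the interaction make 5 comparisons. Gene lists, 32 in all, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, and lists with fewer than 5 tested members received counts only. With an estimated correlation 2 lists passed in the wild type sleep deprivation comparison, 1 in the knockout one and 0 in each of the other 3. List scores are the mean over members of the log2 deviation from the average library. Overlaps used Fisher's exact test.

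The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Kcnma1, then for each pairwise comparison the 10 highest and 10 lowest called genes whose groups did not overlap and whose mean level was above the median, without placeholder symbols, then up to 4 members per list with the smallest p, the 5 smallest p of the interaction, and called genes within 10 Mb of Kcnma1. A gene that the rule named is not reported here. Gm6768, Stbd1, Tmem260, Gm15446 and the genes on chromosomes 14 and Y were named after their values were seen. Gene positions came from GENCODE M21 on GRCm38, in which 22647 of 22880 gene identifiers were matched.

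Alternatives were median-of-ratios, TMM and quantile scaling, other pseudocounts and filters, limma-voom and DESeq2 1.42.0 on recovered reads, 1 model of all 16 libraries, no trend or robust step, the replicate number in the model, and leaving out each library in turn. Tests with edgeR 4.0.16 on recovered reads, and without KO_BL 1, KO_SD 1 and KO_SD 4, were added after seeing the data. The edgeR quasi-likelihood test on recovered reads called 188 genes for sleep deprivation in wild type, 35 in knockout, 2 and 0 for knockout against wild type at baseline and after sleep deprivation, and 0 for the interaction.

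The fits were tested on simulated counts with the sizes of these libraries, with 100 genes changed 1.5-fold and 100 changed 2-fold. Genes were drawn independently around the mean of the wild type or baseline group, with 1 dispersion per gene over all groups. The simulation held no tissue or length shift and no group with a larger spread, so recovery in the real libraries can differ. For sleep deprivation in wild type, run on 14220 genes, limma recovered 53% of the 1.5-fold and 85% of the 2-fold changes. For sleep deprivation in knockout, on 14202 genes, it recovered 17% and 70%. For knockout against wild type it recovered 44% and 90% at baseline (14242 genes) and 16% and 68% after sleep deprivation (14172 genes). For the interaction, on 14508 genes, it recovered 5% and 52%. Unchanged genes called by limma numbered 9, 7, 10, 4 and 1 in the same order.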

Results

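Total RNA of the brain cortex was sequenced from 16 individual mice of an F1 cross of C57Bl6/J and Sv129. The mice were either deficient in the BK channel, a calcium- and voltage-activated potassium channel whose pore-forming subunit is encoded by Kcnma1, or wild type littermates. Mice of each genotype were left undisturbed (baseline) or kept awake by gentle handling for 4 h from light onset, and tissue was taken at zeitgeber time 4. The 4 groups of 4 mice are written WT_BL, WT_SD, KO_BL and KO_SD, with the replicate number after the group where a single library is meant. The number of reads recovered from the deposited normalized counts was 17845979, 18206110, 24192722 and 21799842 in WT_BL 1 to 4, and 14268903, 23690546, 19432234 and 25498440 in WT_SD 1 to 4. It was 8763800, 23033990, 19172082 and 27100275 in KO_BL 1 to 4, and 16890858, 30502991, 17230375 and 15925318 in KO_SD 1 to 4, so that KO_BL 1 was the shallowest library. Each library came from a separate animal, so limma p-values of single genes measure the spread between animals in groups of 4. List tests at the preset correlation take members as nearly independent, and Fisher's exact tests count genes, so the p-values of both rest on genes rather than animals. The labels do not say which animals shared a cage or a litter.

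Kcnma1 (ENSMUSG00000063142, chromosome 14, 23289431 to 24014491, minus strand, GRCm38) was counted in every library. Its normalized counts were 1779, 1317, 1889 and 1151 in WT_BL 1 to 4 and 1108, 822.7, 912.3 and 1583 in WT_SD 1 to 4. They were 2156, 1425, 2047 and 1600 in KO_BL 1 to 4 and 2004, 1113, 801.5 and 432.2 in KO_SD 1 to 4. The group means were 1534 ± 356 in WT_BL, 1106 ± 339 in WT_SD, 1807 ± 350 in KO_BL and 1088 ± 671 in KO_SD (SD, n = 4 each). Kcnma1 did not differ between libraries labelled knockout and wild type at baseline (log2 fold change 0.245 ± 0.178 SE, limma with Benjamini-Hochberg adjusted p = 0.982) or after sleep deprivation (-0.19 ± 0.39 SE, adjusted p = 1). Without KO_SD 4 the value after sleep deprivation was 0.18, with an adjusted p of 0.985. The part of the gene removed in the knockout allele is not given in the sources used here, and a count over the whole gene includes reads from outside a deleted part, so this count does not check the genotype labels. Every genotype direction given here therefore rests on the labels.

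**Figure D1:**
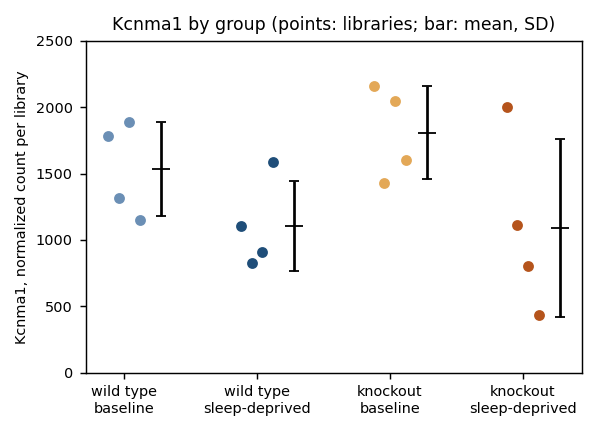
Normalized count of Kcnma1 (vertical axis) in each of the 16 libraries, by group, with the group mean and SD over 4 libraries. The groups overlap, and KO_SD has the widest range, from 432.2 to 2004.

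In wild type mice, 4 h of sleep deprivation raised immediate early genes, which neurons switch on in response to activity. Homer1, which encodes a postsynaptic scaffold protein and has a short activity-induced form, rose from 3504 ± 352 to 7951 ± 391 normalized counts (SD, n = 4 each), a log2 fold change of 1.19 ± 0.0858 SE (limma with Benjamini-Hochberg adjusted p = 0.000219). The transcription factor genes Fosb (1.53 ± 0.176 SE), Nr4a3 (1.23 ± 0.144), Fosl2 (1.18 ± 0.156) and Crem (0.70 ± 0.0889) rose, as did Bdnf, which encodes a neurotrophin (1.05 ± 0.158), with limma adjusted p = 0.00216, 0.00249, 0.00511, 0.00383 and 0.00922. All 39 measured members of the immediate early list had a higher mean after sleep deprivation, with a median log2 fold change of 0.79. Of these, 11 passed over all genes tested, 25 passed adjusted over the list alone, and 28 did not pass over all genes. The list test with limma's camera gave an adjusted p = 3.83e-20, and an adjusted p = 0.152 with an estimated correlation.

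Genes for chaperones of the endoplasmic reticulum rose together in the sleep-deprived wild type mice. Hspa5, which encodes the chaperone BiP, went from 4282 ± 411 to 8205 ± 457 normalized counts (SD, n = 4 each), a log2 fold change of 0.94 ± 0.0852 SE (limma adjusted p = 0.000615). Pdia4, a protein disulfide isomerase gene, rose by 0.91 ± 0.0743 SE on the log2 scale, Manf by 0.83 ± 0.077 and Sdf2l1 by 1.16 ± 0.124, with limma adjusted p = 0.000414, 0.000648 and 0.00156. All 20 members of the list were higher, with a median of 0.45. Of them 11 passed over all genes and 16 adjusted over the list alone (camera adjusted p = 1.17e-18, and adjusted p = 0.0254 with an estimated correlation). The cytosolic heat shock list passed too, with 19 of 19 members higher, a median of 0.33, 6 members past the threshold over all genes and 13 adjusted over the list alone (camera adjusted p = 4.83e-11, and adjusted p = 0.0425 with an estimated correlation). Among them Hspa8 rose by 0.48 ± 0.0673 SE, Hsph1 by 0.46 ± 0.0685, Dnajb5 by 0.64 ± 0.108 and Hspb1 by 1.30 ± 0.217, with limma adjusted p = 0.00701, 0.00922, 0.0172 and 0.0172. Cirbp, a gene induced by mild cooling, fell by 0.64 ± 0.113 SE (limma adjusted p = 0.0224). Over 21 alternative settings the calls of Hspa8, Hsph1, Hspb1, Dnajb5 and Cirbp ended in 1, 2, 2, 5 and 7 (limma adjusted p up to 0.0501, 0.0888, 0.0755, 0.0647 and 0.0981), for the last 4 of these without WT_SD 3 among others.

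Glucocorticoid-responsive genes were higher in all 18 tested members in sleep-deprived wild type mice, with a median log2 fold change of 0.53. Cdkn1a, which encodes a cell cycle inhibitor, rose from 289.8 ± 56.6 to 886.1 ± 167 normalized counts (SD, n = 4 each), a log2 fold change of 1.61 ± 0.162 SE (limma adjusted p = 0.00106). Sult1a1, a sulfotransferase gene, rose by 1.47 ± 0.18 SE, Plin4, which encodes a lipid droplet protein, by 2.75 ± 0.385 and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 0.88 ± 0.164, with limma adjusted p = 0.00351, 0.00713 and 0.0274. Over all genes 5 members passed, and 9 adjusted over the list alone (camera adjusted p = 7.46e-11, and adjusted p = 0.0969 with an estimated correlation). Clock genes moved in both directions. Per2, a repressor of the circadian clock, rose by 0.90 ± 0.11 SE, Bhlhe40 by 0.54 ± 0.093 and Nfil3 by 0.65 ± 0.12, while Dbp, a clock output gene, fell by 0.61 ± 0.116 (limma adjusted p = 0.00351, 0.0203, 0.0268 and 0.0309). The clock list did not pass as a whole, with 10 of 20 members higher, 4 members higher and 1 lower adjusted over the list alone, and a camera adjusted p = 0.196. Over 21 alternative settings the calls of Plin4, Tsc22d3, Bhlhe40, Nfil3 and Dbp ended in 2, 6, 6, 6 and 7 (limma adjusted p up to 0.0664, 0.111, 0.0874, 0.116 and 0.149), for all but Plin4 without WT_BL 2, WT_BL 3, WT_BL 4 or WT_SD 3 among others.

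Ion channel and receptor lists were lower after sleep deprivation in wild type mice by small amounts. Among the 57 other potassium channel genes 46 were lower, with a median log2 fold change of -0.20 (camera adjusted p = 3.58e-05, and adjusted p = 0.364 with an estimated correlation). Kcnh2, which encodes an ERG-type potassium channel, fell by 0.62 ± 0.126 SE, and Kcnn2, which encodes a small-conductance calcium-activated potassium channel, rose by 0.56 ± 0.119 (limma adjusted p = 0.0366 and 0.0474). These were the only 2 listed potassium channel genes to pass over all genes, against 1 higher and 9 lower adjusted over the list alone. Listed voltage-gated sodium and HCN channel genes had a median of -0.27 over 13 members (camera adjusted p = 0.00149, and adjusted p = 0.364 with an estimated correlation), with 0 past the threshold over all genes and 5 adjusted over the list alone. Calcium channel genes had a median of -0.17 over 18 members, ionotropic glutamate receptors -0.15 over 15 and GABA receptors -0.12 over 14, with camera adjusted p = 0.011, 0.0256 and 0.0106 and adjusted p = 0.424, 0.364 and 0.468 with an estimated correlation. The GABA receptor subunit gene Gabrd fell by 0.55 ± 0.114 SE (limma adjusted p = 0.0421). Over 21 alternative settings the calls of Kcnh2, Kcnn2 and Gabrd ended in 7, 10 and 10 (limma adjusted p up to 0.239, 0.179 and 0.143), each of them without WT_BL 1, 3 or 4 or WT_SD 3, Kcnh2 and Gabrd without WT_BL 2, and Kcnn2 and Gabrd without WT_SD 1 or 2. Adjusted over the list alone, 1 calcium channel gene, 2 glutamate receptor genes and 2 GABA receptor genes passed. Leaving out WT_BL 1 gave camera adjusted p = 0.05 for the calcium channels and 0.0905 for the glutamate receptors, and leaving out WT_SD 2 gave 0.0782 for the glutamate receptors and 0.055 for the GABA receptors, which were at 0.0702 without WT_BL 3. The calcium channel median was -0.11 without WT_SD 1 and the GABA receptor median -0.20 without WT_SD 4. Across the 14310 genes the log2 fold change had a Spearman correlation of -0.186 with transcript length, where genes are not independent replicates.

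Markers of neighbouring tissue and signs of RNA composition moved with the treatment in the same wild type libraries. All 11 tested striatal marker genes were lower in WT_SD, with a median log2 fold change of -1.12 and 0 past the threshold over all genes and 7 adjusted over the list alone (camera adjusted p = 4.5e-06, and adjusted p = 0.364 with an estimated correlation). The striatal adenosine receptor gene Adora2a had a log2 fold change of -2.61 ± 0.626 SE (limma adjusted p = 0.0823). Without WT_BL 1 the striatal median was -0.69. The mean striatal score ran from -0.63 to 1.62 in WT_BL and from -1.13 to -0.36 in WT_SD. All 11 hippocampal marker genes were higher, with a median of 0.765, 0 past the threshold over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00162, and adjusted p = 0.424 with an estimated correlation). The hippocampal median was 0.46 without WT_SD 3 and 1.16 without WT_SD 4. Cytosolic ribosomal protein genes had a median of 0.22 with 76 of 81 members higher (camera adjusted p = 2.9e-10, and adjusted p = 0.471 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Without WT_BL 1 the ribosomal median was 0.145. Mitochondrial ribosomal RNA took 0.767% ± 0.0885 of the reads in WT_BL and 1.13% ± 0.151 in WT_SD (SD, n = 4 each). Blood genes had a median of -0.77 over 5 members (camera adjusted p = 0.000213, and adjusted p = 0.364 with an estimated correlation), with 1 past the threshold over all genes and 4 adjusted over the list alone. Alas2, which encodes the erythroid enzyme of heme synthesis, fell by 1.14 ± 0.188 SE (limma adjusted p = 0.0165), a call that ended in 4 of 21 alternative settings, among them without WT_BL 3, WT_BL 4 or WT_SD 3 (adjusted p up to 0.116).

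In total 194 of 14310 tested genes passed in wild type mice, 122 higher and 72 lower after sleep deprivation (limma with Benjamini-Hochberg adjustment), and 2495 had an unadjusted p below 0.05, where 716 were expected by chance. The 4 libraries of each group did not overlap at 1477 genes, or 10.3%, against 2.86% by chance. Within the naming rule (mean level above the median, groups that did not overlap), the largest increases also included Tshz2 (1.23 ± 0.185 SE), Pcsk1, which encodes a prohormone convertase (0.94 ± 0.118), and Gjb6, which encodes the astrocyte gap junction protein connexin 30 and belongs to the astrocyte list (0.92 ± 0.081), with limma adjusted p = 0.011, 0.00383 and 0.000588. By the same rule the largest decreases included Dact2 (-0.89 ± 0.165 SE), Rasgef1b (-0.87 ± 0.111), Rassf3 (-0.80 ± 0.139), B3galt1 (-0.77 ± 0.155), Hecw2 (-0.73 ± 0.109), the histamine receptor gene Hrh3 (-0.73 ± 0.132) and Dcx, which encodes doublecortin (-0.61 ± 0.119). Their limma adjusted p values were 0.0268, 0.00392, 0.0207, 0.0365, 0.00904, 0.0245 and 0.0343. Over 21 alternative settings the calls of Pcsk1, Dact2, Rassf3, B3galt1, Hecw2, Hrh3 and Dcx ended in 1, 6, 6, 8, 1, 7 and 7 (limma adjusted p up to 0.142, 0.0916, 0.0835, 0.371, 0.0682, 0.187 and 0.305), for all but Pcsk1 and Hecw2 without WT_BL 4 or WT_SD 3 among others. The authors' deposited table listed 642 genes at a false discovery rate below 0.05, which included all 194 in the same direction. The count was 91, 73, 60 and 81 without WT_BL 1, 2, 3 or 4, and 106, 133, 46 and 508 without WT_SD 1, 2, 3 or 4. The balance of directions moved as well, from 51 higher and 9 lower without WT_BL 3 to 209 higher and 299 lower without WT_SD 4. It was 79 with all 16 libraries in 1 model, 102 without the trend and robust steps and 663 with DESeq2 on recovered reads. The model of all 16 libraries takes the noisier KO_SD libraries into its spread.

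In mice labelled knockout, sleep deprivation raised immediate early genes and chaperone genes as well. Fosb rose by 1.55 ± 0.173 SE on the log2 scale, Fosl2 by 1.32 ± 0.183, Nr4a3 by 1.38 ± 0.224 and Dusp5, a phosphatase gene, by 1.25 ± 0.149 (limma with Benjamini-Hochberg adjusted p = 0.0128, 0.0257, 0.0377 and 0.0128). Ptgs2, which encodes cyclooxygenase 2, rose from 294 ± 35.4 to 768.6 ± 239 normalized counts (SD, n = 4 each), Nptx2, which encodes a neuronal pentraxin, from 1037 ± 152 to 2381 ± 318 and Bdnf from 588.8 ± 95.1 to 1379 ± 330 (limma adjusted p = 0.0257, 0.0128 and 0.03). Of the 39 immediate early genes 38 were higher, with a median log2 fold change of 0.70. Of them 9 passed over all genes and 28 adjusted over the list alone (camera adjusted p = 1.91e-23, and adjusted p = 0.0475 with an estimated correlation). All 20 endoplasmic reticulum chaperone genes were higher, with a median of 0.585, 5 past the threshold over all genes and 14 adjusted over the list alone (camera adjusted p = 8.66e-17, and adjusted p = 0.133 with an estimated correlation). Hspa5 rose by 0.955 ± 0.144 SE, Pdia4 by 0.92 ± 0.15, Creld2 by 0.996 ± 0.152 and Xbp1, a transcription factor gene of the unfolded protein response, by 0.86 ± 0.127 (limma adjusted p = 0.03, 0.0377, 0.03 and 0.0285). Over 22 alternative settings the calls of Fosb, Fosl2, Nr4a3, Dusp5, Ptgs2, Nptx2 and Bdnf ended in 3, 5, 9, 3, 5, 3 and 7 (limma adjusted p up to 0.0609, 0.107, 0.136, 0.0649, 0.111, 0.0867 and 0.114) and those of Hspa5, Pdia4, Creld2 and Xbp1 in 5, 9, 6 and 5 (up to 0.126, 0.172, 0.134 and 0.125), each of them without KO_BL 2 or KO_SD 3 among others. Heat shock genes had a median of 0.42 with 18 of 19 higher, 0 past the threshold over all genes and 11 adjusted over the list alone (camera adjusted p = 2.87e-10, and adjusted p = 0.133 with an estimated correlation).

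Cdkn1a rose from 357.9 ± 55 to 995.5 ± 87.4 normalized counts in mice labelled knockout (SD, n = 4 each), a log2 fold change of 1.48 ± 0.139 SE (limma adjusted p = 0.00641). It was the only glucocorticoid-responsive gene of 18 to pass over all genes, against 3 adjusted over the list alone, and the list's median was 0.24 (camera adjusted p = 0.000842, and adjusted p = 0.31 with an estimated correlation). Tshz2 rose by 1.33 ± 0.215 SE and Kcnn2 by 0.73 ± 0.119 (limma adjusted p = 0.0377 for each). Hcn4, which encodes a hyperpolarization-activated channel, fell by 2.06 ± 0.292 SE and Erich3 by 0.98 ± 0.13 (limma adjusted p = 0.0257 and 0.0224). Over 22 alternative settings the calls of Cdkn1a, Tshz2, Kcnn2, Hcn4 and Erich3 ended in 2, 10, 9, 6 and 5 (limma adjusted p up to 0.0609, 0.186, 0.177, 0.107 and 0.107), each of them without KO_BL 2 or KO_SD 3. Listed voltage-gated sodium and HCN channel genes had a median of -0.36 over 13 members, with 1 lower over all genes and 2 adjusted over the list alone (camera adjusted p = 5.27e-05, and adjusted p = 0.223 with an estimated correlation). Other potassium channel genes had a median of -0.225 over 57 members (camera adjusted p = 0.00148, and adjusted p = 0.464 with an estimated correlation). Calcium channel genes had a median of -0.27, ionotropic glutamate receptors -0.20 and GABA receptors -0.13, with camera adjusted p = 0.00846, 0.0128 and 0.0254 and adjusted p = 0.575, 0.432 and 0.575 with an estimated correlation. Without KO_SD 4 the medians were -0.24 for the sodium and HCN, -0.13 for the other potassium and -0.093 for the calcium channels and -0.12 for the glutamate receptors, with camera adjusted p = 0.000983, 0.0263, 0.288 and 0.0915. The GABA receptor median was -0.23 without KO_SD 1, and its camera adjusted p was 0.115, 0.0887, 0.0995 and 0.144 without KO_BL 1, KO_BL 3, KO_SD 2 or KO_SD 3.

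Tissue composition and library quality also varied among the libraries labelled knockout. Striatal markers had a median of -0.73 with 11 of 11 members lower after sleep deprivation (camera adjusted p = 0.000352, and adjusted p = 0.464 with an estimated correlation), and hippocampal markers a median of 0.48 with 9 of 10 higher (camera adjusted p = 0.00165, and adjusted p = 0.133 with an estimated correlation). Ribosomal protein genes had a median of 0.29 over 81 members (camera adjusted p = 4.29e-08, and adjusted p = 0.661 with an estimated correlation), and their mean score per library ran from -0.47 in KO_SD 1 to 0.85 in KO_SD 4. Their median was 0.071 without KO_SD 4 (camera adjusted p = 0.0331) and 0.52 without KO_SD 1. Blood genes were lower in 5 of 5 members, with a median of -0.97 and 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.00932, and adjusted p = 0.558 with an estimated correlation). The blood median was -0.63 without KO_SD 1, with an adjusted p of 0.117, and -0.54 without KO_BL 2. Mitochondrial ribosomal RNA took 0.728% ± 0.0726 of the reads in KO_BL and 1.25% ± 0.468 in KO_SD (SD, n = 4 each), with 1.89% in KO_SD 4. Across the 14318 genes the log2 fold change had a Spearman correlation of -0.312 with transcript length.

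Over all genes 33 of 14318 passed in mice labelled knockout, 27 higher and 6 lower (limma with Benjamini-Hochberg adjustment), and 1765 had an unadjusted p below 0.05, where 716 were expected by chance. The 4 libraries of each group did not overlap at 1178 genes, or 8.23%, against 2.86% by chance. The authors' deposited table listed 302 genes at a false discovery rate below 0.05, which included all 33 in the same direction. The count was 18, 0, 2 and 3 without KO_BL 1, 2, 3 or 4 and 70, 8, 0 and 35 without KO_SD 1, 2, 3 or 4, so leaving out KO_BL 2 or KO_SD 3 ended every call, and without KO_SD 1 it was 34 higher and 36 lower. It was 220 with all 16 libraries in 1 model and 315 with DESeq2 on recovered reads. The model of all 16 libraries pools the spread over groups, which is too small for the noisier KO_SD. The count was 383, 175 higher and 208 lower, without KO_BL 1, KO_SD 1 and KO_SD 4, which were chosen after seeing the data because of their depth and ribosomal scores. This left only KO_SD 2 and KO_SD 3 in their group, without either end of its ribosomal scores. The higher count may follow from that choice.

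The responses of the 2 genotypes were set side by side over 14214 genes tested in both, in comparisons that share no library. Among genes called higher, 122 in wild type and 27 in mice labelled knockout, 18 were called in both, against 0.232 for independent lists (two-sided Fisher's exact test p = 7.61e-32). Those 18 included Cdkn1a, Tshz2, the immediate early genes Nr4a3, Fosl2, Bdnf, Fosb, Dusp5 and Ptgs2, the chaperone list members Hspa5, Pdia4, Creld2, Sdf2l1 and Xbp1, and Kcnn2. Among genes called lower, 69 and 6, there were 2 in both, Pla2g4e and Scn7a, a sodium channel gene outside the tested channel lists, named after their values were seen, against 0.0291 (two-sided Fisher's exact test p = 0.000344), and 0 genes were called in opposite directions. Of the 191 genes called in wild type, 189 (99%) had the same sign in mice labelled knockout, against 78.2% of all 14214 genes. Their median ratio of the knockout to the wild type log2 fold change was 0.887. Genes picked for a call in 1 genotype favour that genotype's value. Over the 33 genes called in mice labelled knockout, the median ratio of the wild type to the knockout value was 0.86. Over all genes the median absolute log2 fold change was 0.134 in wild type mice and 0.17 in mice labelled knockout. Across all genes the log2 fold changes had a Pearson correlation of 0.695 and a Spearman correlation of 0.701, where genes are not independent replicates. Striatal and hippocampal markers and the trend on transcript length also moved the same way in both genotypes. The agreement does not separate sleep deprivation from these. The median standard error was 0.12 in wild type mice and 0.174 in mice labelled knockout. The count of 20 shared genes was 10, 0, 2 and 2 without KO_BL 1, 2, 3 or 4, 5 and 0 without KO_SD 2 or 3, and 12 without the filter on low values. It was 67 without KO_BL 1, KO_SD 1 and KO_SD 4, a choice that takes out both ends of the KO_SD ribosomal scores.

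**Figure D2:**
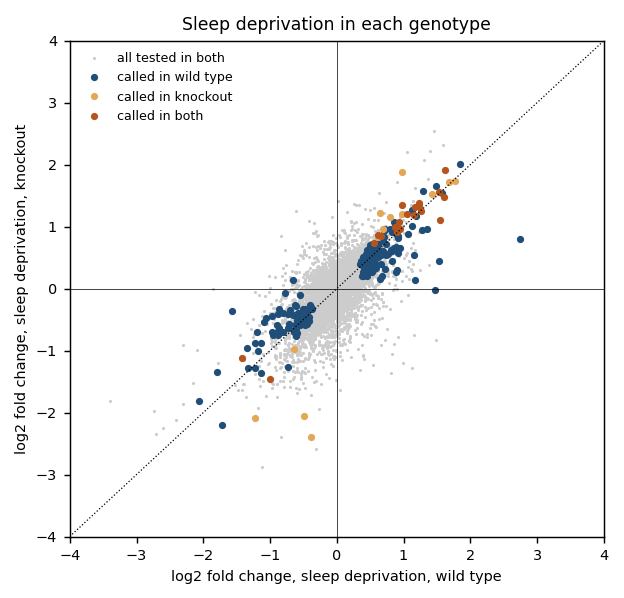
Log2 fold change after sleep deprivation in wild type mice (horizontal axis) and in mice labelled knockout (vertical axis) for the 14214 genes tested in both, with genes past the threshold coloured by the genotype in which they passed and a dotted line of equal change. Of the 191 genes called in wild type, 189 lie on the same side of 0 in both genotypes, against 78.2% of all genes.

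**Figure D3:**
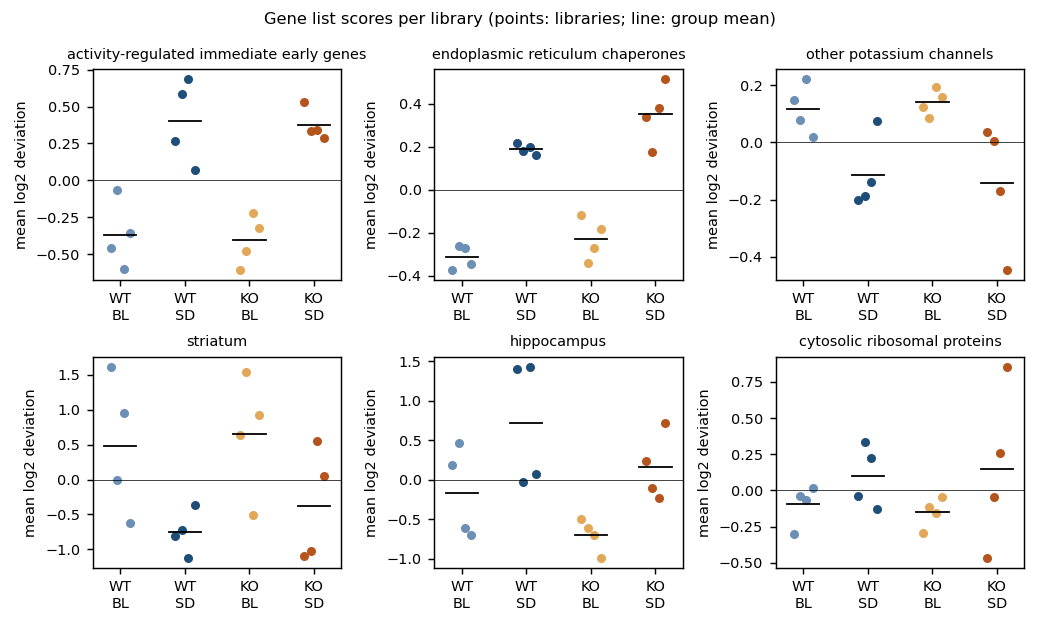
Mean log2 deviation from the average of all libraries over the members of 6 gene lists, for each of the 16 libraries (points) by group, with the group mean as a line. Immediate early scores ran from -0.61 to -0.067 at baseline and from 0.073 to 0.69 after sleep deprivation, while ribosomal scores in KO_SD ran from -0.47 to 0.85.

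At baseline, mice labelled knockout and wild type littermates differed at 2 of 14341 genes (limma with Benjamini-Hochberg adjustment), both named after their values were seen. Gm6768 (ENSMUSG00000021908, chromosome 12, 119260978 to 119262855, GRCm38), a processed pseudogene whose reads can be shared with its parent gene, had 62.4 ± 7.65 normalized counts in WT_BL and 1.73 ± 2.16 in KO_BL (SD, n = 4 each), a log2 fold change of -4.92 ± 0.531 SE (limma adjusted p = 0.0135). Its means were 2.8 ± 2.27 in WT_SD and 2.84 ± 1.97 in KO_SD, so it was high in WT_BL only and did not follow the genotype labels after sleep deprivation. Stbd1 (ENSMUSG00000047963, chromosome 5, 92603041 to 92606579, GRCm38), which encodes a starch-binding protein of glycogen metabolism, had 29.2 ± 2.83 in WT_BL and 125 ± 54.6 in KO_BL, a log2 fold change of 1.98 ± 0.25 SE (limma adjusted p = 0.0318). An unadjusted p below 0.05 was found for 395 genes, where 717 were expected by chance, and 255 genes, or 1.78%, did not overlap between groups, against 2.86% by chance. The authors' deposited table listed 3 genes, Gm6768, Stbd1 and Tmem260. Of the 119 tested genes within 10 Mb of Kcnma1, 0 passed by limma (two-sided Fisher's exact test p = 1). With only 2 genes called in all, this says little about differences linked to Kcnma1.

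The count of 2 was 0, 0, 1 and 0 without WT_BL 1, 2, 3 or 4 and 1, 1, 2 and 1 without KO_BL 1, 2, 3 or 4. Neither gene was called when a WT_BL library was left out, and the 1 gene called without WT_BL 3 was Gm15446 (4.685 ± 0.302 SE, limma adjusted p = 0.00015), named after its values were seen. Gm6768 was then not tested, since it no longer reached the minimum level in 4 libraries, and Stbd1 had limma adjusted p = 0.306, 0.306, 0.0888 and 0.298 without WT_BL 1, 2, 3 or 4. The 1 gene called without KO_BL 1, 2 or 4 was Gm6768. Oligodendrocyte precursor markers were lower in 9 of 10 members in KO_BL, with a median of -0.19 (camera adjusted p = 0.00559, and adjusted p = 0.886 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Without KO_BL 4 this list had an adjusted p of 0.063. Hippocampal markers had a median of -0.28, excitatory neuron markers -0.13, endoplasmic reticulum chaperones 0.077 and sterol synthesis genes 0.092, with camera adjusted p = 0.0211, 0.029, 0.02 and 0.0426. Those were adjusted p = 0.886, 0.886, 0.944 and 0.944 with an estimated correlation. Leaving out KO_BL 1 ended the calls of the chaperone, sterol and excitatory neuron lists (adjusted p = 0.122, 0.0555 and 0.0507), WT_BL 1 those of the chaperone, sterol and hippocampal lists (0.153, 0.153 and 0.0807) and KO_BL 4 those of the chaperone, sterol and hippocampal lists (0.159, 0.125 and 0.223). WT_BL 2 ended those of the sterol, excitatory neuron and hippocampal lists (0.328, 0.0915 and 0.0915), WT_BL 3 and KO_BL 2 that of the excitatory neurons (0.0521 and 0.203) and KO_BL 3 that of the sterol genes (0.179). The chaperone median was 0.04 without KO_BL 1, the sterol median 0.058 and 0.06 without WT_BL 2 or KO_BL 3, the excitatory neuron median -0.20 without KO_BL 4 and the hippocampal median -0.435 without WT_BL 1.

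After sleep deprivation, 0 of 14280 genes differed between mice labelled knockout and wild type littermates by limma, 232 had an unadjusted p below 0.05, where 714 were expected by chance, and edgeR, limma-voom and DESeq2 on recovered reads each called 0. The authors' deposited table listed 0 genes as well. The groups did not overlap at 193 genes, or 1.35%, against 2.86% by chance. Some lists passed together without any member passing alone. All 20 endoplasmic reticulum chaperone genes were higher in KO_SD than in WT_SD, with a median of 0.16 (camera adjusted p = 4.17e-07, and adjusted p = 0.387 with an estimated correlation). Glucocorticoid-responsive genes were lower in 16 of 18 members, with a median of -0.24 (camera adjusted p = 2.84e-05, and adjusted p = 0.299 with an estimated correlation), led by Plin4 at -1.26 ± 0.408 SE (limma adjusted p = 1). Without WT_SD 4 the list's median was -0.16. Astrocyte markers were lower in 12 of 13 members, with a median of -0.15 (camera adjusted p = 0.00124, and adjusted p = 0.294 with an estimated correlation). Adjusted over the list alone, 0 members of these 3 lists passed.

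Hippocampal markers were lower in 10 of 11 members in KO_SD than in WT_SD, with a median of -0.55 (camera adjusted p = 3.96e-05, and adjusted p = 0.426 with an estimated correlation), and striatal markers were higher in 10 of 11, with a median of 0.36 (camera adjusted p = 0.00555, and adjusted p = 0.653 with an estimated correlation). The striatal call ended without KO_SD 3 or KO_SD 4 (adjusted p = 0.623 and 0.073), and its median was 0.093 without KO_SD 3 and 0.54, 0.57 and 0.65 without WT_SD 4, KO_SD 1 or KO_SD 2. The hippocampal median was -0.26, -0.34 and -0.36 without WT_SD 1, WT_SD 3 or KO_SD 3. Heat shock genes had a median of 0.13, sterol synthesis genes 0.10 and nuclear-encoded respiratory chain genes 0.12, with camera adjusted p = 0.000318, 0.00364 and 0.00109 and adjusted p = 0.426, 0.299 and 0.794 with an estimated correlation. All of these calls ended without KO_SD 4, with adjusted p = 0.104, 0.0595 and 0.262, the respiratory chain median then being -0.048 and the heat shock median 0.053. Without KO_SD 2 those medians were 0.185 and 0.21, and without KO_SD 1 the respiratory chain median was 0.23. The respiratory chain call also ended without WT_SD 4 (adjusted p = 0.0513). None of the 117 tested genes within 10 Mb of Kcnma1 passed by limma, which follows from the absence of any called gene in this comparison.

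The interaction asks whether the response to sleep deprivation differed between genotypes, and 0 of 14604 genes passed by limma, with 160 at an unadjusted p below 0.05, where 730 were expected by chance. edgeR and limma-voom on recovered reads called 0, and DESeq2 called 1, Gm6768. Its mean was 62.4 normalized counts in WT_BL, 2.8 in WT_SD, 1.73 in KO_BL and 2.84 in KO_SD (n = 4 each). Its interaction and its baseline call thus rest on the same high WT_BL values. The 5 smallest p values belonged to Gm6768 (4.90 ± 0.9 SE), Ldb3 (-0.97 ± 0.227), Omd (-2.17 ± 0.584), Sult1a1 (-1.49 ± 0.413) and Aurka (1.86 ± 0.527), with limma adjusted p = 0.633 for Gm6768 and 1 for the others. Glucocorticoid-responsive genes had a median interaction of -0.23, with 15 of 18 members below 0, 0 past the threshold over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000147, and adjusted p = 0.578 with an estimated correlation). Among them were Plin4 (-1.95 ± 0.904 SE), Mertk (-0.50 ± 0.21) and Fkbp5 (-0.485 ± 0.235), each with a limma adjusted p = 1. The immediate early list had a median interaction of 0.024, the endoplasmic reticulum chaperones 0.08 and the heat shock genes 0.056, with camera adjusted p = 0.671, 0.073 and 0.224.

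Ribosomal protein genes had a median interaction of 0.10, with 73 of 81 members above 0 and 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0415, and adjusted p = 0.823 with an estimated correlation). Without KO_SD 4 the median was -0.13, with an adjusted p of 5.47e-05, and it was 0.31, 0.18, 0.18 and 0.16 without KO_SD 1, WT_SD 2, KO_SD 2 or WT_BL 1. The call ended without WT_BL 2, 3 or 4 (adjusted p = 0.137, 0.0892 and 0.135), WT_SD 1 or 4 (0.24 and 0.52), KO_BL 1 or 3 (0.166 and 0.115) and KO_SD 3 (0.249). The list scores per library show the same spread, with KO_SD 1 and KO_SD 4 at the ends of the KO_SD range.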

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

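The tests of chromosome 14, of a weaker response in mice labelled knockout and of striatal RNA in each genotype taken apart were chosen only after the result was seen.

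Other splits of the same libraries were counted for each comparison. For sleep deprivation in wild type mice, 1 of the 35 splits into 4 and 4, the real one, gave as many as 194 genes, and the highest other gave 9. In mice labelled knockout it was 1 of 35 as well, with 33 genes against 4 for the highest other. With 35 splits the smallest possible share is 1 of 35, so chance is made less likely for both counts but not excluded. The splits also do not separate sleep deprivation from the tissue composition that moved with it. At baseline, 2 of 35 splits gave as many as the real 2 genes, and the highest other gave 5, so chance cannot be excluded. After sleep deprivation, 35 of 35 splits gave as many as the real 0 genes, with 27 for the highest other, which set WT_SD 1, 2 and 3 with KO_SD 4 against the rest. Any split gives as many as 0, so this count could not argue for or against chance. The split with 27 was the only one to call any gene and was picked for its count, so it does not show a structure among these libraries. For the interaction, 100 of 100 drawn assignments gave as many as the real 0 genes, as any assignment must, with 9 for the highest other.

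Mice labelled knockout and wild type littermates differed at baseline more often on chromosome 14, which carries Kcnma1, where 10 of 484 tested genes (2.07%) had an unadjusted p below 0.01, against 0.346% elsewhere (two-sided Fisher's exact test, adjusted over 5 comparisons p = 0.000106). A strain variant linked to the targeted gene may leave the same differences in the independent sleep-deprived groups, and 66.7% of 9 genes had the same direction there, against 80.9% of 47 genes elsewhere, too few genes to decide. Their median absolute log2 fold change was 0.553 at baseline, and 0.115 in the baseline direction after sleep deprivation. Elsewhere these were 0.508 and 0.162. Picking genes for their baseline difference lowers the later value in both sets. A mislabelled sample was tested by placing each WT_SD library between the WT_BL mean at 0 and the KO_BL mean at 1 over the 10 genes, and the medians were 0.763, 0.705, 0.701 and 1.061, with 0.701 the lowest, against 0.983, 0.868, 0.835 and 0.585 in KO_SD 1 to 4 at the same genes and -0.222 to 0.492 in WT_SD over 48 genes elsewhere. By these medians WT_SD and KO_SD both lay nearer to KO_BL than to WT_BL. WT_BL thus stood apart at these genes, and the difference did not follow the genotype labels after sleep deprivation. Neither explanation is decided, since these chromosome 14 genes were picked for their baseline difference and the labels give no strain per library. Sleep deprivation in wild type mice, which uses the same WT_BL libraries, gave an excess there too, with 50 of 481 genes (10.4%) against 6.45% elsewhere (adjusted p = 0.0034), while it was 14 of 484 (2.89%) against 3.66% in mice labelled knockout, 0 of 477 against 0.232% between genotypes after sleep deprivation and 3 of 503 (0.596%) against 0.184% for the interaction (adjusted p = 0.572, 0.627 and 0.128).

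Sleep deprivation called 194 genes in wild type mice and 33 in mice labelled knockout, although the interaction called 0. Sequencing depth is argued against, since thinning every wild type library to 8.76 M reads, the shallowest depth, left a median of 152.5 called genes (137 to 180 over 20 draws). A weaker response in the knockout stays open, since the median interaction log2 fold change was 0.06 over 78 immediate early, endoplasmic reticulum chaperone and heat shock genes but -0.228 over 18 glucocorticoid-responsive genes, and the interaction of the libraries' mean score was 0.04 ± 0.115 SE (-0.019 to 0.089 with 1 library left out) and -0.376 ± 0.189 SE (-0.24 ± 0.142 without KO_BL 2). A larger spread among the libraries of the knockout comparison remains. With 1 spread from all 16 libraries the counts were 79 in wild type and 220 in knockout, a ratio of 0.359. A pooled spread is too small for the noisier comparison and too large for the other. The counts then shift this way whatever the responses, so they do not weigh the spread against a genotype difference. The larger spread itself is seen in the residual SDs. It lay in KO_SD and not in KO_BL. The median residual SD on the log2 scale was 0.252 in the knockout comparison and 0.248 between genotypes after sleep deprivation. It was 0.174 in the wild type comparison and 0.176 between genotypes at baseline. The counts of 194 and 33 may follow from that larger spread, which does not exclude a genotype difference at part of the genes.

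All 10 tests of 5 ion channel and receptor lists in 2 genotypes were lower and past the threshold after sleep deprivation. Gene length bias may contribute, since 5 of the 10 stayed so after each library's trend on transcript length was removed. All 10 medians then stayed below 0 but came nearer to it. They were -0.194 to -0.09 in wild type mice and -0.235 to -0.093 in mice labelled knockout. With the striatum score as a covariate 6 of the 10 stayed lower and past the threshold, among them all 5 in mice labelled knockout. Every median there was further from 0 (-0.284 to -0.509, against -0.133 to -0.361), where striatal RNA as the whole cause would bring them nearer. Yet the mean striatal score moved with the treatment there too, from 0.651 in KO_BL to -0.38 in KO_SD. The covariate also shifted the medians the other way in wild type mice, so this test does not decide. The larger medians may rest in part on KO_SD 4, which had the lowest KO_SD score for every one of these lists but the GABA receptors. The covariate was not tried without that library. In wild type mice 1 of 5 stayed lower and past the threshold with the covariate, with medians of -0.154 to 0.03 against -0.267 to -0.121. Striatal RNA and gene length cannot be told apart from sleep deprivation itself in either genotype. The striatal score moved with the treatment in both. The counts of 6 with the covariate and 5 after the length correction lay between the bounds set beforehand. None of the 10 tests passed with an estimated correlation.

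Single libraries stood far from the other 3 of their group in 9 of 264 groups of values examined. Chance gives about 1 in 20, so there was no excess, and the values are listed only as a description. KO_SD 2 had 30.5 M recovered reads against 15.9 to 17.2 M. Tshz2 was at 1421 normalized counts in WT_BL 2 against 719.1 to 828.9. Pcsk1 was at 964.4 in KO_BL 1 against 612.5 to 665.2, and Dcx at 1508 in the same library against 772.2 to 854.6. Dact2 was at 486.5 in WT_SD 1 against 757.8 to 810.3. Omd was at 19.65 in KO_SD 2 against 6.174 to 8.232. The cold-inducible score was 0.789 in KO_BL 2 against 0.217 to 0.314, the glutamate receptor score 0.166 in KO_BL 4 against 0.054 to 0.073, and the synaptic score 0.073 in WT_SD 4 against -0.056 to -0.041.

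The difference in response between genotypes passed for 2 lists with the preset correlation, the glucocorticoid-responsive genes (median interaction -0.228, camera adjusted p = 0.000147) and the ribosomal protein genes (0.101, camera adjusted p = 0.0415). The adjusted p was 0.578 and 0.823 with an estimated correlation. The ribosomal value was -0.134 without KO_SD 4, the library with the highest ribosomal score, and 0.311, 0.183, 0.176 and 0.162 without KO_SD 1, WT_SD 2, KO_SD 2 or WT_BL 1, and its call ended without WT_BL 2, 3 or 4, WT_SD 1 or 4, KO_BL 1 or 3 or KO_SD 3 (adjusted p = 0.137, 0.0892, 0.135, 0.24, 0.52, 0.166, 0.115 and 0.249).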

How the results depend on the processing

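The tests with edgeR and those without KO_BL 1, KO_SD 1 and KO_SD 4 were chosen after the result was seen. Over 219 settings of the results that answer a comparison, 152 stayed within 1.5 times the reported value and 67 moved further. A reported 0 that stayed 0 counted among the 152, though it shows no stability of a call. This was so in every setting of the genotype comparison after sleep deprivation and of the genes near Kcnma1, and in most settings of the interaction. Over 2140 settings of named genes and lists, 1783 kept their direction and side of the threshold, 351 lost the threshold, 3 gained it and 3 turned direction. The cause of these changes was not tested, except that leaving out libraries lowers the number of animals.

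With all 16 libraries in 1 model the count of sleep deprivation genes was 79 in wild type and 220 in knockout, and 1 at baseline between genotypes. The pooled spread of that model is too small for the knockout comparison and too large for the wild type one. Without trend and robust steps the count was 102 in wild type and 0 at baseline. DESeq2 called 663 in wild type, 315 in knockout and 1 for the interaction. Leaving out KO_BL 1, KO_SD 1 and KO_SD 4 gave 383 in knockout, 1 at baseline, 1 for the interaction and 67 shared genes. That choice takes out both ends of the KO_SD ribosomal scores, so the higher counts may follow from it. A smaller pseudocount gave 0 at baseline, limma-voom gave 1 there, and a pseudocount 5 times as large gave 1 for the interaction. Without the filter the shared genes were 12 and the interaction lists 1. With an estimated correlation the lists past the threshold were 2 in wild type, 1 in knockout, and 0 for the baseline, sleep-deprived and interaction comparisons.

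Leaving out each library in turn gave 46 to 508 genes in wild type, 0 to 70 in knockout, 0 to 2 at baseline, 0 to 26 shared genes, and 1 to 8, 8 to 16 and 1 to 9 lists for the baseline, sleep-deprived and interaction comparisons. The respiratory chain list after sleep deprivation ran from -0.048 to 0.229, the ribosomal interaction from -0.134 to 0.311 and the Kcnma1 genotype difference after sleep deprivation from -0.557 to 0.179, each turning direction without KO_SD 4 and at its other end without KO_SD 1.

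With the replicate number as a block the counts were 230 in wild type, 47 in knockout, 2 at baseline, 0 after sleep deprivation and 0 for the interaction, and 31 shared genes. The lists past the threshold were then 18, 16, 4, 11 and 3 in the same order, against 16, 16, 5, 8 and 2, and the call of the baseline sterol list ended (camera adjusted p = 0.0617). Of the reported genes 159 of 194 in wild type, 31 of 33 in knockout and 2 of 2 at baseline were called with the block, so 35 and 2 calls ended, among them that of Insig1 in wild type (limma adjusted p = 0.0665), while 71 and 16 other genes were called. Of 16 pairs of libraries with the same number 6 had correlated deviations above 0.1, over a range of -0.401 to 0.376, and 5 correlated best with their own number, so the numbers do not pair the animals by a rule that asks for every pair. As a hint from the data only, the 4 pairs with number 1 were at 0.252, 0.376, 0.219 and 0.323, each best with its own number.

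KO_BL 1, at 8.76 M reads, limits the precision of low genes in its group.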

Other observations

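Cell type lists outside the main comparisons moved little in single genes. In mice labelled knockout, 13 of 13 oligodendrocyte markers were higher after sleep deprivation, with a median log2 fold change of 0.39 and 0 past the threshold over all genes and 3 adjusted over the list alone (limma camera adjusted p = 1.82e-05, and adjusted p = 0.464 with an estimated correlation). Without KO_BL 3 the median was 0.25. The myelin genes Ermn (0.62 ± 0.174 SE), Mal (0.61 ± 0.18) and Mobp (0.58 ± 0.169) had limma adjusted p = 0.212, 0.228 and 0.228. In wild type mice 11 of 13 were higher, with a median of 0.21 (camera adjusted p = 0.0725), and the interaction had a median of 0.16 with 13 of 13 members above 0 (camera adjusted p = 0.0581). Astrocyte markers rose in wild type mice as a list, with a median of 0.15 and 11 of 13 members higher (camera adjusted p = 0.00475, and adjusted p = 0.438 with an estimated correlation, or 0.0673 without WT_BL 4), 1 of them past the threshold over all genes and 2 adjusted over the list alone. The astrocyte median was 0.25 without WT_BL 1 and 0.072 without WT_BL 4. Microglial markers had a median of 0.01 in wild type mice and -0.074 in mice labelled knockout (camera adjusted p = 0.887 and 0.417).

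Single genes of other cell types passed in wild type mice. Vip, which encodes a neuropeptide of interneurons, rose by 0.48 ± 0.103 SE on the log2 scale, Ly6c1, expressed in endothelium, by 0.76 ± 0.126 and the vesicular glutamate transporter gene Slc17a6 by 0.69 ± 0.118 (limma adjusted p = 0.0487, 0.0165 and 0.0187). Insig1, a regulator of sterol synthesis, fell by 0.40 ± 0.0853 SE (limma adjusted p = 0.0481). Over 21 alternative settings the calls of Vip, Ly6c1, Slc17a6 and Insig1 ended in 14, 3, 4 and 11 (limma adjusted p up to 0.184, 0.0766, 0.305 and 0.186), that of Vip with any of the 8 libraries left out, that of Insig1 with any but WT_SD 4, that of Ly6c1 without WT_BL 2, WT_BL 3 or WT_SD 3 and that of Slc17a6 without WT_BL 1 or WT_SD 3. The sterol synthesis list was lower in 16 of 21 members in each genotype, with a median of -0.12 in wild type mice and -0.17 in mice labelled knockout (camera adjusted p = 0.00381 and 0.0219, and adjusted p = 0.364 and 0.31 with an estimated correlation). Its wild type median was -0.185 and -0.08 without WT_BL 2 or WT_BL 3, and its knockout call ended without KO_BL 1, KO_BL 3, KO_SD 1 or KO_SD 2 (adjusted p = 0.0735, 0.0637, 0.0781 and 0.0656). Nuclear-encoded respiratory chain genes were higher in 28 and 27 of 30 members, with medians of 0.125 and 0.25 (camera adjusted p = 0.000777 and 0.000506, and adjusted p = 0.525 and 0.661 with an estimated correlation). Without WT_BL 1 the wild type median was 0.074, and the knockout median was 0.39 without KO_SD 1 and 0.057 without KO_SD 4, where its call ended (adjusted p = 0.222).

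Gm15446 (chromosome 5, 109923400 to 109943936, GRCm38), named after its values were seen, ran from 6.977 to 577.3 normalized counts over the 16 libraries, with 6 libraries below 50, 4 from 200 to 300 and 6 above 300. The Y-linked genes Kdm5d, Uty, Eif2s3y and Ddx3y were below 50 in all 16 libraries, with Ddx3y from 5.94 to 33.59.

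The 10 chromosome 14 genes with the smallest p at baseline included Tmem260 (357 ± 12.8 normalized counts in WT_BL and 492 ± 28.1 in KO_BL, SD, n = 4 each), Ldb3 (99.1 ± 21.6 and 169 ± 19.9), Ncoa4 (474 ± 39.2 and 637 ± 58.5) Myh6 (17.7 ± 6.81 and 3.15 ± 2.63), Cmtm5 (567 ± 67.2 and 398 ± 50.9) and Klhl1 (70.3 ± 15.7 and 113 ± 25.9). Their limma adjusted p was 0.982 each. In WT_SD 8 of the 10 means lay on the KO_BL side of the WT_BL mean and 2 on the other, and in KO_SD it was 8 and 2 as well. The WT_SD means were 498 ± 82.1 for Tmem260, 159 ± 15 for Ldb3, 605 ± 72.2 for Ncoa4 and 3.48 ± 1.14 for Myh6, each on the KO_BL side, and 657 ± 142 for Cmtm5 and 49.3 ± 10.3 for Klhl1, each on the other side. In KO_SD they were 474 ± 76.2 for Tmem260, 140 ± 19 for Ldb3, 591 ± 152 for Ncoa4, 2.23 ± 1.82 for Myh6, 616 ± 206 for Cmtm5 and 69.1 ± 19.2 for Klhl1.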
